A study of Bos taurus with 12 samples.

How the data were processed

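Small RNA was measured by sequencing in blood samples of 12 cows, 6 heat resistant and 6 heat stressed, and the group of each library was taken from its group label. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with a TruSeq small RNA kit and sequenced on an Illumina HiSeq instrument, and the raw reads were filtered with the ACGT101-miR program, which took out adapter dimers, junk, low complexity reads, reads of common RNA families and repeats. Those filters are meant to remove rRNA, tRNA, snRNA and snoRNA before counting. The totals below are therefore totals of reads assigned to miRNA rows and not of all reads. Rows whose sequence is shared with such RNAs can remain, as does miR-1246, whose sequence is also found in U2 snRNA. The aligner, the miRBase release and the genome build are not given in the sources used here, and no coordinates are printed. The protocol text speaks of 9 libraries, while the series and the table hold 12, all of which were used, and which of these that text covers is not given in the sources used here. The labels do not say whether whole blood, cells or plasma was extracted.

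The deposited table holds expected counts, since per the file headers its raw columns are read counts per miRNA row and the values need not be whole. Of the values above 0, 74.7% were whole (within 1e-06) and the others were not. A second set of deposited columns, normalized counts (a signal), is 1 constant times the raw values of each library, from 0.692 to 1.70; how the authors derived it is not given in the sources used here, and these columns entered no test. The table has 2183 rows with 1981 distinct names. The 202 repeat rows belong to 175 names that stand on several rows with the same values, and each was counted once. Of the values of names on 2 rows, 41.1% were whole as deposited and 84.1% after doubling, so each row seems to carry an equal part of the reads; summing the rows was tried as an alternative. The planned rule of counting each mature sequence once was applied by name, as sequences were not used here. The names comprise 754 cattle features (98.2% of counts), 719 predicted candidates (0.140%) and 508 named for other species (1.64%). Suffixes that mark isoforms in the table are left out of the names in the text. In 120 names the values matched those of another name in 3 or more libraries (miR-16a and miR-16b, miR-17-5p and miR-106a), so reads shared by near-identical miRNAs cannot be attributed to 1 of them. Values of 0 make up 42.9% of the table. In rows with whole values only, 99.7% of the values above 0 were 5 or more, so a 0 may stand for a few reads.

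Total counts ran from 4395454 to 10601301 per library. Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with its default minimum count of 10, TMM factors, quasi-likelihood F test with robust=TRUE) and Benjamini-Hochberg adjustment at 0.05, 2-sided. The filter kept 756 features (445 cattle, 80 predicted, 231 of other species names). Log2 fold changes are heat stressed over heat resistant, SE is the log2 fold change divided by the root of the F statistic, and CPM are counts scaled to the TMM-adjusted library total. On simulated data made from these libraries, with 200 of the 756 features changed, the test recovered 68 of 100 changes of 2-fold and 90 of 100 changes of 4-fold, and called 3 of 556 unchanged features. The simulated counts were drawn independently for each feature, without the variation that features share in real libraries, so the rates need not hold there.

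The 16 miRNA lists covered blood cell types (red cell, platelet, myeloid, lymphocyte), other tissues (liver, muscle, epithelium), families and clusters (let-7, miR-17-92, miR-30, miR-34 with miR-449, DLK1-DIO3, miR-2284 with miR-2285), responses (inflammation, hypoxia) and candidates recalled from earlier work on heat-stressed cattle. They, the tests and the rule for named miRNAs were fixed before the data were examined. Lists were tested with camera (inter-gene correlation 0.01, limma 3.58.1), adjusted over the 16, with fry and an estimated correlation as alternatives. The 20 measures per library were compared by exact permutation of the 12 libraries and adjusted over the 20. The separation of the whole profile was tested over all 462 splits, on log2 CPM with a prior count of 2, and arm usage with limma on log2 ratios of 5' to 3' products with the same prior, after leaving out precursors whose arms had the same values throughout. A form whose name gives no arm was taken as the other arm only where 1 arm had no labelled form, and in 9 of 160 precursors the most abundant form was therefore in neither arm of the ratio.

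Named miRNAs are the 8 cattle features with the smallest p in each direction (none passed, where the rule would have taken up to 15), the 10 most abundant features, and the most abundant members of each list (4 in lists past the threshold, 2 in others, of up to 4 allowed); a few more are named in the text as chosen after their values were seen. In the table the 16 are bta-miR-6524_R+1, bta-miR-29a_L-1R-1, bta-miR-342_R-2, bta-mir-150-p3, bta-miR-32_R-2, bta-miR-11971_1ss15TC, bta-miR-142-5p_L+2R-1, bta-miR-2336_R-1, bta-miR-455-3p_L-1_1ss22TC, bta-miR-324, bta-miR-455-5p_R+1, bta-miR-149-5p_R-2, bta-mir-2285s-p5_1ss17TC, bta-miR-95, bta-miR-11982_R+2 and bta-mir-2904-2-p5. Alternatives covered the scaling (DESeq2 size factors, upper quartile, totals only), the tool (DESeq2 1.42.0, limma-voom), filters, the empirical Bayes setting, the replicate number as a block, a red cell covariate, leaving out each library, feature definitions and thresholds. A planned change of the pseudocount in log2 of values plus 1 was for tables with normalized values alone and was not run, while the planned change of the prior count of arm ratios was run.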

Results

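Small RNA was sequenced from the blood of 12 Chinese Holstein dairy cows, 6 classed by the study as heat resistant and 6 classed as heat stressed. The classes came from a principal component analysis of rectal temperature and the loss of milk yield. The series lists 12 libraries, taken here as 1 per cow, while its protocol text speaks of 9. The heat resistant libraries, numbered 1 to 6, held 8256189, 6934458, 4395454, 10601069, 6841147 and 7405071 counts. The heat stressed libraries held 7808354, 9052898, 10601301, 8194097, 7518265 and 6935781 counts, and the exact permutation p for the difference in total was 0.344. A heat stressed library had counts in 1139 ± 75.1 features and a heat resistant library in 1069.8 ± 119 (SD, n = 6 each; exact permutation p = 0.247).

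A small set of miRNAs held much of the counts. The most abundant was miR-21-5p, a broadly expressed miRNA that is induced in inflammation, with 9.26 ± 1.36% and 8.98 ± 1.63% of counts in heat stressed and heat resistant cows (SD, n = 6 each). In the same order of groups, miR-423-5p held 5.34 ± 0.334% and 4.96 ± 0.620%, miR-192 held 4.36 ± 0.409% and 4.47 ± 0.922%, and miR-191 held 4.01 ± 0.345% and 4.01 ± 0.598%. The hepatocyte miRNA miR-122 held 2.21 ± 1.08% and 5.84 ± 6.02% (SD, n = 6 each). Heat resistant libraries 1 and 2 had 147829.6 and 158426 CPM of miR-122, against 9327 to 45460.0 CPM in the other 10 libraries. let-7g held 4.07 ± 0.577% and 3.45 ± 0.508%, and miR-486, abundant in red cells, held 3.59 ± 1.27% and 2.33 ± 1.94% (SD, n = 6 each). Shares of miR-22-3p were 2.82 ± 0.231% and 2.94 ± 0.353%, those of miR-25 were 3.18 ± 0.668% and 2.20 ± 0.986%, and those of miR-221 were 2.56 ± 0.345% and 2.89 ± 0.833% (SD, n = 6 each). The smallest adjusted p among these 10 features was 0.213 (edgeR), for miR-25 and miR-122. The 10 most abundant features of each library held 43.0 ± 1.10% in heat stressed and 43.9 ± 3.46% in heat resistant libraries (SD, n = 6 each).

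miR-29a, miR-342, a product of miR-150 and miR-142-5p had higher values in heat stressed cows, although edgeR called no miRNA with all libraries. The first 3 are miRNAs of lymphocytes, a list that did not pass camera (adjusted p = 0.254), with 13 higher and 14 lower features. miR-29a, which is high in mature lymphocytes, stood at 23386 ± 5882 against 13598 ± 2018 CPM in heat stressed and heat resistant cows (SD, n = 6 each). Its log2 fold change was 0.78 ± 0.17 (SE), with an adjusted p of 0.0674. miR-342, another miRNA of lymphocytes, stood at 6017 ± 1695 against 3183 ± 866 CPM (SD, n = 6 each; log2 fold change 0.92 ± 0.21, SE; edgeR adjusted p = 0.0686). The 3' product of the precursor of miR-150, a miRNA that restrains MYB in lymphocytes, stood at 113 ± 38.1 against 53.1 ± 16.1 CPM (SD, n = 6 each; log2 fold change 1.09 ± 0.26, SE; edgeR adjusted p = 0.0686). miR-142-5p, made across the blood cell lineages, stood at 32107 ± 6695 against 17958 ± 6572 CPM (SD, n = 6 each; log2 fold change 0.84 ± 0.21, SE; edgeR adjusted p = 0.0692).

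Higher values were also seen for miR-6524 (log2 fold change 0.99 ± 0.21, SE; adjusted p = 0.0674), miR-32 (0.97 ± 0.23; 0.0686), miR-11971 (0.62 ± 0.16; 0.0692) and miR-2336 (1.07 ± 0.28; 0.0721). Both arms of miR-455, a miRNA of cartilage and brown fat, had lower values in heat stressed cows. miR-455-3p stood at 17.4 ± 3.43 against 38.8 ± 18.5 CPM and miR-455-5p at 55.5 ± 12.2 against 109.7 ± 49.5 CPM (SD, n = 6 each). Their log2 fold changes were -1.16 ± 0.27 and -0.98 ± 0.26 (SE), with adjusted p of 0.0686 and 0.0721. miR-324 stood at 9.83 ± 3.17 against 22.5 ± 8.41 CPM (SD, n = 6 each; log2 fold change -1.19 ± 0.31, SE; edgeR adjusted p = 0.0721). Log2 fold changes were -0.92 ± 0.27 for miR-149-5p, -0.66 ± 0.20 for miR-95 and -0.85 ± 0.26 for miR-11982 (SE). They were -1.40 ± 0.41 for the 5' product of miR-2285s and -1.18 ± 0.38 for that of miR-2904-2 (SE), and the adjusted p of the lower 8 ran up to 0.107. For each of these 16 miRNAs all 6 heat stressed libraries lay on the same side of the heat resistant median, which their choice by the smallest p in these libraries makes likely.

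**Figure D1:**
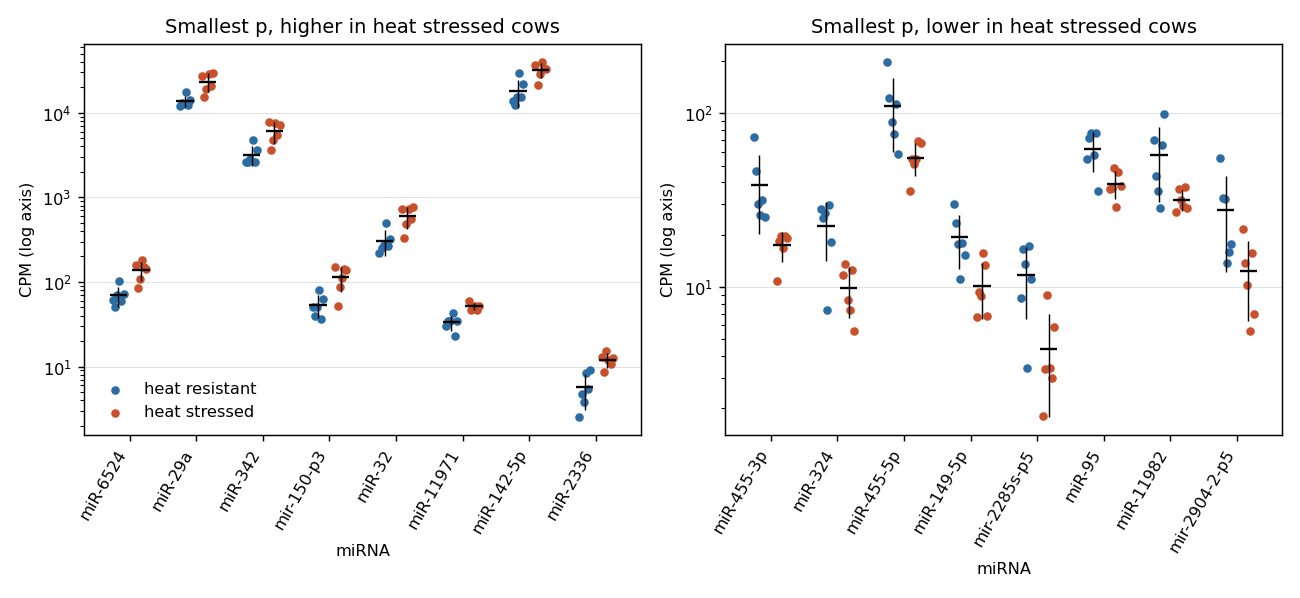
CPM (log axis) of the 8 cattle miRNAs with the smallest p on each side, in heat stressed and heat resistant cows; each point is 1 library, with the mean and SD of each group (n = 6). All 6 heat stressed values of miR-455-3p lie below all 6 heat resistant values, and no miRNA shown had an adjusted p under 0.05.

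With edgeR, 0 of 756 features had an adjusted p under 0.05. An unadjusted p under 0.05 was reached by 146 features, 69 with higher and 77 with lower values in heat stressed cows, where 37.8 would come by chance. DESeq2 called 54 features (30 higher, 24 lower) and limma-voom 0. Without heat resistant library 4, edgeR called 97 (65 higher, 32 lower), among them all 8 named miRNAs with higher values and 7 of the 8 with lower values. Without heat stressed library 2 it called 29 (22 higher, 7 lower). Without heat resistant library 5 it called 2 with lower values, 2 names of miR-6240 products that hold the same values, named after these were seen. On the first principal component heat resistant library 4 lay among the heat stressed libraries, and heat stressed library 2 lay nearest to the other group. Leaving either out widens many differences by construction. The named miRNAs were also chosen by p in these same libraries, so the calls without either library, here and below, are no separate evidence. In 8 features the groups did not overlap, where 1.64 would come by chance.

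miRNAs of red cells had higher values in heat stressed cows in 22 of 24 tested features, with a median log2 fold change of 0.37 (camera adjusted p = 0.000739; adjusted p = 0.566 with an estimated correlation). miR-486 stood at 39251 ± 14381 against 25272 ± 21393 CPM, and miR-451, needed for the maturation of red cells, at 11877 ± 4753 against 9186 ± 7722 CPM (SD, n = 6 each). Log2 fold changes were 0.64 ± 0.39 for miR-486, 0.37 ± 0.39 for miR-451, 0.55 ± 0.23 for miR-25 and 0.25 ± 0.13 for miR-92a (SE). No member passed over all features, and 0 passed when adjusted over the list alone. As a share of counts the list held 11.1 ± 2.60% in heat stressed and 7.89 ± 4.37% in heat resistant libraries (SD, n = 6 each; exact permutation p = 0.165, adjusted 0.366). Heat resistant library 4 had 16.7%, against 5.14% to 6.99% in the other 5 of its group. Without that library 12 members were called, all higher in heat stressed cows, with log2 fold changes of 1.26 ± 0.23 for miR-486 and 0.98 ± 0.24 for miR-451 (SE). Its share was the highest of all libraries, so leaving it out raises these differences by construction, and the calls are no separate evidence for them.

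The miR-17-92 cluster and its paralogs, which drive proliferation, had higher values in 19 of 21 features, with a median log2 fold change of 0.26 (camera adjusted p = 0.00517; adjusted p = 0.566 with an estimated correlation). Log2 fold changes were 0.35 ± 0.18 for miR-93 and 0.11 ± 0.14 for miR-20a (SE). miR-20b, named after its values were seen, was the only member that passed when adjusted over the list alone (0.69 ± 0.19, SE). Over all features edgeR called 6 members without heat resistant library 4 and 2 without heat stressed library 2. Heat resistant library 4 had 8.03% of its counts in this list, against 3.85% to 5.25% in the others of its group. Leaving it out therefore raises the difference by construction, and the 6 calls are no separate evidence. The list and the red cell list shared 7 features. Without these, the unadjusted camera p was 0.000740 for the other 17 red cell features and 0.0169 for the other 14 features of the clusters; with an estimated correlation these were 0.221 and 0.294. The log2 ratio of miR-451 to miR-23a, the planned red cell covariate, was 0.38 ± 0.74 in heat stressed and -0.86 ± 1.40 in heat resistant libraries (SD, n = 6 each; exact permutation p = 0.0887). With this ratio as a covariate neither list passed, and the adjusted p of the red cell list was 0.184.

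The share of counts in the lymphocyte list rose, with 4.07 ± 0.677% in heat stressed and 2.99 ± 0.308% in heat resistant libraries (SD, n = 6 each; exact permutation p = 0.00216, the smallest the permutations can give; adjusted 0.0433). The lowest heat stressed library had 3.36% and the highest heat resistant library 3.29%. miR-29a carried most of this, with 2.13 ± 0.479% against 1.26 ± 0.191% of counts (SD, n = 6 each). The rest of the list, taken after these values were seen, held 1.94 ± 0.296% against 1.73 ± 0.282% (SD, n = 6 each; exact permutation p = 0.242, adjusted 0.494). Of 27 members 13 were higher and 14 lower. The median log2 fold change was -0.03 while the mean was 0.17 and camera pointed up. Adjusted over the list alone, 10 features passed with higher and 2 with lower values. Mature miR-150 was among the higher, at 2595 ± 1179.9 against 1433 ± 563 CPM (SD, n = 6 each), as were miR-29a, miR-342, miR-29b (0.47 ± 0.14, SE) and miR-181a-2-3p (0.67 ± 0.26, SE). The lower were miR-181d (-0.51 ± 0.17, SE) and miR-181c (-0.43 ± 0.15, SE), so that the miR-181 family, active in T cell development, went both ways. These 3 miR-181 products, miR-29b and mature miR-150 were named after their values were seen. miR-26b stood at 7965 ± 2215 against 9282 ± 2219 CPM (SD, n = 6 each; edgeR adjusted p = 0.565).

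The miR-34 family, direct targets of p53, had higher values in all 4 tested features, with a median log2 fold change of 0.75 (camera adjusted p = 0.0183; adjusted p = 0.453 with an estimated correlation). miR-34c stood at 43.1 ± 16.5 against 21.8 ± 7.17 CPM and miR-34a at 42.0 ± 11.1 against 32.6 ± 4.99 CPM (SD, n = 6 each). The 3' arm of miR-34b stood at 4.18 ± 1.78 against 1.39 ± 0.667 CPM and that of miR-34c at 2.37 ± 1.61 against 1.64 ± 0.963 CPM (SD, n = 6 each). Both lie near the floor. Heat resistant values of the former ran from 0.788 to 2.59 CPM, and the latter was 0 in heat resistant library 1. Counts above 0 but under 5 are rare in the table, so the fold changes of these 3' arms are uncertain. miR-34c and the 3' arm of miR-34b passed when adjusted over the list alone. The share of the list rose, with 0.00849 ± 0.00202% in heat stressed and 0.00534 ± 0.000897% in heat resistant libraries (SD, n = 6 each; exact permutation p = 0.00433, adjusted 0.0433). That call was lost when the 3 most abundant features were left out of the totals. The camera adjusted p was 0.0678 without heat resistant library 4 and 0.0512 without heat stressed library 5. Over all features edgeR called miR-34c and the 3' arm of miR-34b without heat resistant library 4 (adjusted p = 0.0223 for each). It also called them without heat stressed library 2 (0.0474 and 0.0364), and called miR-34a and the 3' arm of miR-34c in neither fit.

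The miR-2284 and miR-2285 families of ruminants had higher values in 58 of 75 features, with a median log2 fold change of 0.28 (camera adjusted p = 0.00328; adjusted p = 0.566 with an estimated correlation). The most abundant member, miR-2284x, stood at 4121 ± 452 against 3199 ± 517 CPM (SD, n = 6 each; edgeR adjusted p = 0.151). Log2 fold changes were 0.41 ± 0.18 for the 3' product of miR-2284w, 0.14 ± 0.21 for miR-2284ab and 0.42 ± 0.17 for miR-2285k (SE). No member passed when adjusted over the list alone. Without heat resistant library 4 edgeR called miR-2284x over all features (adjusted p = 0.0281) and some less abundant members, among which the 5' product of miR-2285s was lower.

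**Figure D2:**
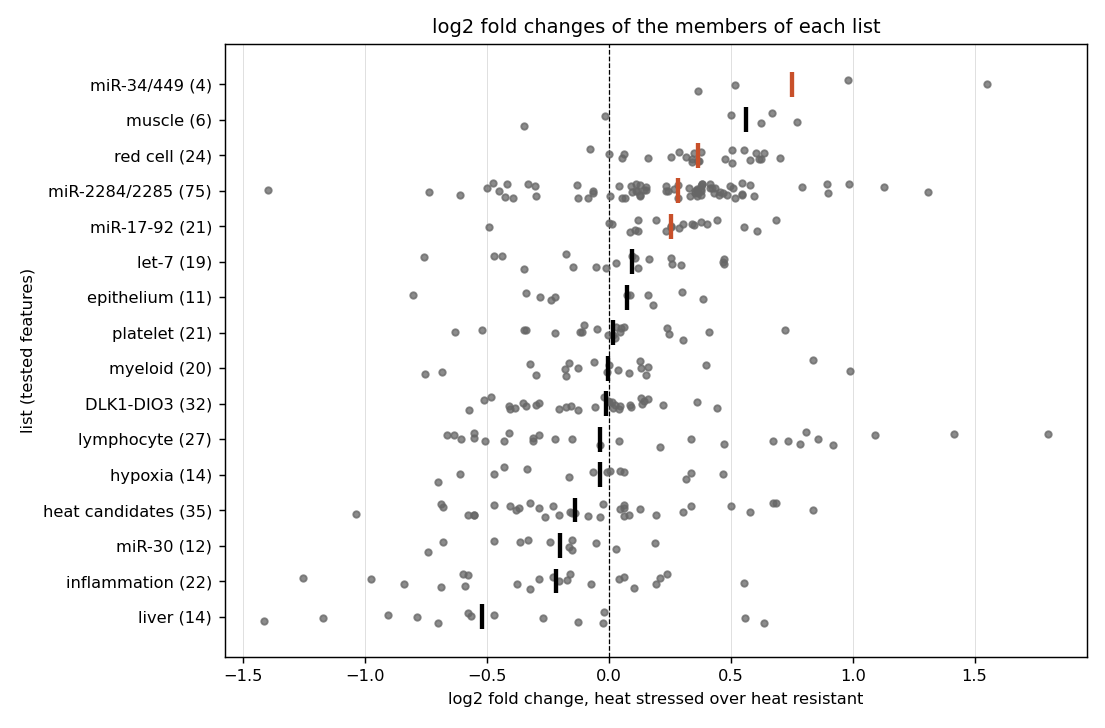
Log2 fold change, heat stressed over heat resistant, of every tested member (points) of the 16 miRNA lists, with the median of each list as a bar. The lists with a camera adjusted p under 0.05 at the preset correlation have medians from 0.26 to 0.75, and none of them passed with an estimated correlation.

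Liver miRNAs had 2 higher and 12 lower features (camera adjusted p = 0.248), with log2 fold changes of -1.42 ± 0.60 for miR-122 and -0.02 ± 0.15 for miR-192 (SE). The list held 17.6% and 20.3% of counts in heat resistant libraries 1 and 2. It held 4.92% to 7.65% in the others of that group and 5.59% to 8.71% in heat stressed libraries. A lower share in heat stressed cows thus rests on heat resistant libraries 1 and 2. Without heat resistant library 6 the adjusted p of that list was 0.0242 (0.556 with an estimated correlation). Muscle miRNAs had 4 higher and 2 lower (adjusted p = 0.254), with miR-206, specific to skeletal muscle, at 151 ± 146 against 98.8 ± 138 CPM and miR-499 at 223 ± 37.9 against 225 ± 56.3 CPM (SD, n = 6 each). Library 3 of each group had the most miR-206, 424 CPM in heat stressed and 379.9 CPM in heat resistant cows. The adjusted p of the muscle list was 0.000435 without heat resistant library 3 (0.477 with an estimated correlation). It was 0.0486 without heat stressed library 6 and 0.0301 with the red cell covariate (0.717 and 0.703 with an estimated correlation). Platelet miRNAs had 11 higher and 10 lower (adjusted p = 0.900), with log2 fold changes of 0.02 ± 0.10 for miR-191 and -0.05 ± 0.12 for miR-22-3p (SE); the median was 0.02, the mean -0.01, and camera pointed down. Myeloid miRNAs had 9 higher and 11 lower (adjusted p = 0.900); the median was below 0, the mean above 0, and camera pointed down. miR-142-5p alone passed when adjusted over the list alone, and miR-23a stood at 8880.5 ± 2770.3 against 14964 ± 6667 CPM (SD, n = 6 each; edgeR adjusted p = 0.155).

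The epithelial list had 6 higher and 5 lower (adjusted p = 0.900), with -0.24 ± 0.22 for miR-375 and 0.07 ± 0.15 for miR-200a (log2 fold change, SE); its median was 0.07, its mean -0.06, and camera pointed up. The let-7 family had 11 higher and 8 lower (adjusted p = 0.681), with 0.26 ± 0.12 for let-7g and 0.11 ± 0.14 for let-7b. The miR-30 family had 2 higher and 10 lower (adjusted p = 0.122), with miR-30d at 18447 ± 2136 against 23751 ± 4842 CPM and miR-30e-5p at 28867 ± 3329.7 against 28276 ± 4058 CPM (SD, n = 6 each). miRNAs induced by NF-kB or toll-like receptors had 7 higher and 15 lower (adjusted p = 0.122). Among them miR-21-5p had a log2 fold change of 0.06 ± 0.12 and miR-221 of -0.16 ± 0.15 (SE). miR-212-3p (-1.26 ± 0.30, SE), named after its values were seen, was the only one that passed when adjusted over the list alone. Without heat stressed library 6 the adjusted p was 0.0348 for the miR-30 list and 0.0400 for the inflammation list (0.681 and 0.545 with an estimated correlation).

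Hypoxia miRNAs had 6 higher and 8 lower (adjusted p = 0.666), with -0.34 ± 0.18 for miR-26a and -0.43 ± 0.20 for miR-103 (log2 fold change, SE). The imprinted DLK1-DIO3 cluster had 15 higher and 17 lower (adjusted p = 0.254), with 0.16 ± 0.24 for miR-127 and -0.06 ± 0.15 for miR-494. Without heat stressed library 3 that adjusted p was 0.00236 (0.557 with an estimated correlation). Candidates from earlier work on heat-stressed cattle had 14 higher and 21 lower (adjusted p = 0.756), and miR-142-5p and miR-20b passed when adjusted over the list alone. The fry test for change in either direction passed for 6 lists: lymphocyte (0.00570), myeloid (0.0135), miR-2284 with miR-2285 (0.0135), heat candidates (0.0205), miR-17-92 (0.0281) and inflammation (0.0376).

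Over the whole miRNA profile the heat stressed and heat resistant cows were separated. The groups held 17.5% of the sum of squares of log2 CPM, and 4 of 462 splits into 6 and 6 gave as much (exact permutation p = 0.00866, 1-sided; median 8.58%). On the first principal component (26.2% of the variance) heat stressed libraries lay between 1.06 and 11.7. Of the heat resistant libraries 5 lay between -17.9 and -1.57, and library 4, rich in red cell miRNAs, lay at 7.91. Correlations of log2 CPM were 0.949 to 0.977 within the heat resistant group, 0.966 to 0.979 within the heat stressed group and 0.944 to 0.979 between them.

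**Figure D3:**
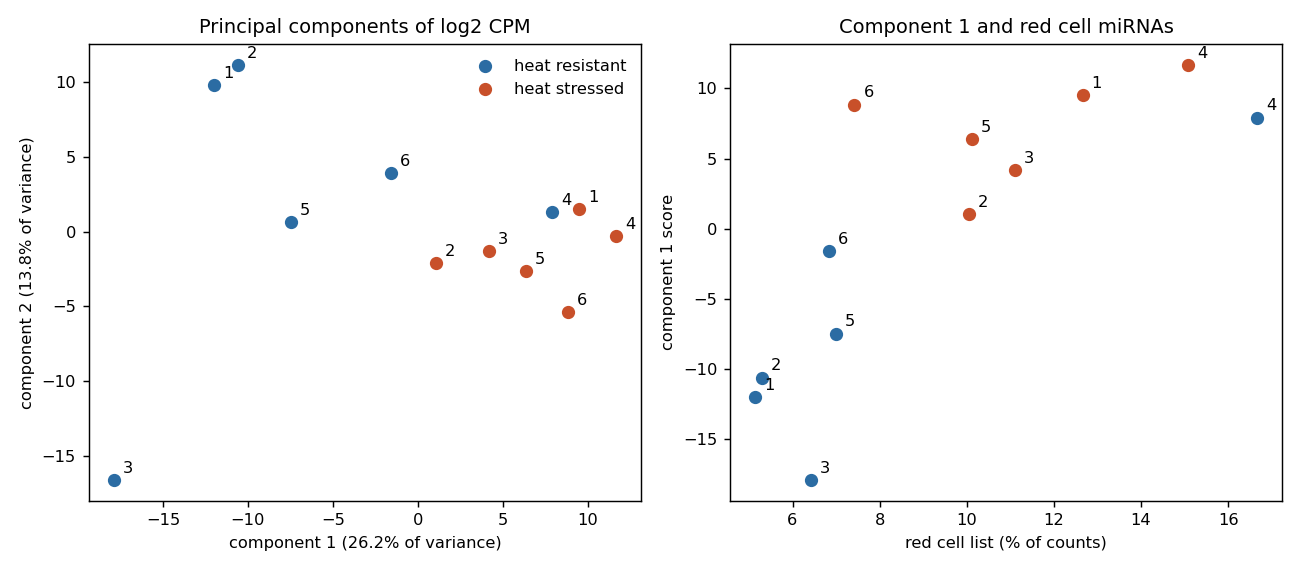
Scores of the 12 libraries on the first 2 principal components of log2 CPM, and the first score against the percent of counts in red cell miRNAs; each point is 1 library, coloured by group. Heat resistant library 4, with 16.7% of counts in red cell miRNAs, lies among the heat stressed libraries.

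The balance between the arms of a precursor differed most by p in miR-378, a miRNA of metabolic tissues. Its log2 ratio of 5' to 3' product was -9.26 ± 0.53 against -8.30 ± 0.09 in heat stressed and heat resistant cows (SD, n = 6 each; limma adjusted p = 0.0698). For miR-215 the ratio was 7.13 ± 0.45 against 6.17 ± 0.29, for miR-27a -10.06 ± 0.47 against -9.14 ± 0.29 and for miR-29d -1.20 ± 0.85 against 0.30 ± 0.51 (SD, n = 6 each), with the same adjusted p. These 4 were named after their p were seen, and none passed: limma called 0 of 160 precursors, with 29 at an unadjusted p under 0.05.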

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

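The comparison of miR-150 and miR-342 with the rest of the lymphocyte list, and the placing of heat resistant library 4 with slopes taken from the other libraries, as well as miR-451 alone and miR-23a alone as covariates, were chosen only after the results were seen.

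In 16 of 178 groups of 6 libraries, 1 library lay far from the other 5 by the Dixon ratio, the gap to the nearest library over the range. About 1 in 20 groups, or 8.90, would by chance. Heat resistant library 4 was the odd library in 7 of them. It was highest in its group in the log2 ratio of miR-451 to miR-23a (Dixon ratio 0.777), in the share of red cell miRNAs (0.839) and in the share of the miR-17-92 list (0.665). Of single miRNAs it was highest in miR-486 (0.817), miR-25 (0.708) and miR-451 (0.702) and lowest in miR-324 (0.646). Heat resistant library 3 was highest in the share of muscle miRNAs (0.834) and in miR-206 (0.834), library 6 in miR-221 (0.714), and library 1 was lowest in the 3' arm of miR-34c (0.734).

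In the heat stressed group library 3 was highest in the share of the DLK1-DIO3 list (0.741) and lowest in miR-30e-5p (0.705). Library 1 was lowest in miR-455-3p (0.724), and library 2 in the 3' arm of miR-34b (0.682) and in miR-342-5p (0.638).

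The higher values of red cell miRNAs in heat stressed cows could come from more red cell RNA in those libraries. With the miR-451 to miR-23a ratio as a covariate the median log2 fold change of the list was 0.12, or 0.330 of its value of 0.37 without it. With miR-451 alone, a member of the list, it was 0.701 of that value and with miR-23a alone, which is not a red cell miRNA, 0.457, so red cell RNA cannot be told apart from other causes by this ratio. After thinning to the smallest total the median was 1.02 times its former value. Random thinning keeps the expected share of each miRNA, so the median could hardly have fallen, and this decides nothing about greater depth as a cause. Whether red cell RNA differs through the cows' physiology or through blood handling was not tested.

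Heat resistant library 4 lay among the heat stressed libraries on the first component. On an axis between the group means built without it, it stood at 0.887, with 0 for heat resistant and 1 for heat stressed, inside the heat stressed range of 0.473 to 1.05, as a mislabelled sample would. After every feature was regressed on the level of the red cell list its score on that component was -5.18; this decides nothing, since the heat stressed libraries then lay at -1.58 to 10.8, 5 of the 6 within the -6.62 to 5.89 of the other heat resistant libraries. On the axis from 0 to 1, with slopes on the red cell level taken from the other libraries, it stood at 1.23 and the other heat resistant libraries at 0.00368 to 0.397, but its red cell level lies above that of every library the slopes came from, so its red cell content cannot be told apart from other causes. A cow with an unusual response in its class would give the same positions, and no test here separates it from a swapped label.

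The members of the lymphocyte list differed in direction. If more lymphocyte RNA were the only cause and every member followed it, the list would have moved with miR-150 and miR-342. Their mean log2 fold change was 0.89, which is 0.922 above the median of the list and more than the SD of its members, 0.699. This comparison was set after the values were seen, and miR-342 was among the miRNAs with the smallest p, so a gap was partly fixed by the choice. More lymphocyte RNA as a part of the change can therefore not be excluded. Over the members tested both before and after thinning the SD was 0.630 and 0.630, a ratio of 1.0. As thinning keeps the expected share of each miRNA, this ratio decides nothing about depth as a source of the spread.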

How the results depend on the processing

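The threshold of 0.10, the summing of rows of 1 name, the thinning to the smallest total, the lymphocyte share less miR-29a, miR-451 and miR-23a alone as covariates, the arm pairs with the most abundant form and the estimated correlation without 1 library were chosen only after the result was seen. The count of called miRNAs was 0 and stayed 0 with 3 other scalings, limma-voom, the non-robust fit, the red cell covariate, unrounded counts, only cattle names, summing without isoform suffix and identical values counted once, with the smallest adjusted p among these 0.0561. It was 54 with DESeq2, 11 without a filter, 16 with a minimum count of 50, 13 with rows of 1 name summed, 13 after thinning and 0 to 97 without 1 library; the cause was not tested. Looser thresholds gave 146 (unadjusted p under 0.05) and 50 (adjusted p under 0.10). Of 4 lists past the threshold, 0 were left with an estimated correlation and 1 with directional fry, both of which allow for correlation between members; without 1 library the count was 3 to 7. Of 2 measures past the threshold 1 was left without the 3 most abundant features. The separation was 23.6% with the stricter filter and 17.5% with totals only. At this depth the test recovered 68 of 100 simulated 2-fold changes. Arm ratios gave 0 calls with a prior count of 0.5 (27 of 160 at an unadjusted p under 0.05) and 0 of 151 when only pairs with the precursor's most abundant form were kept (27). With miR-23a alone as a covariate the adjusted p of the muscle list was 0.00419 (0.729 with an estimated correlation).

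With the replicate number as a block, 8 miRNAs were called and miR-499 had a log2 fold change of 0.00324. Whether the numbers mark pairs of cows or a batch cannot be told from these values. Deviations of libraries of the same number, in place of their whole profiles, had correlations of -0.0527 to 0.277. By these, 5 of 12 libraries correlated best with their own number. Both libraries of number 3 (0.133) and of number 4 (0.277) were among these.

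Of the 67 named features, 14 changed sign under some setting, and the cause was not tested; of these only miR-451 was called in any setting, without heat resistant library 4. For miR-191 the log2 fold change was -0.00259 with DESeq2 size factors, -0.00259 with DESeq2, -0.00514 with totals only, -0.0583 with cattle names only, -0.00900 with rows summed and -0.0338 with identical values counted once. For miR-192 it was 0.00285 with upper quartile factors and 0.000193 with voom, and for miR-499 0.0144, 0.01002 and, without a filter, 0.0240. With the red cell covariate it was -0.161 for miR-451, 0.0700 for miR-26b, 0.0886 for miR-499, 0.179 for miR-375, -0.0597 for miR-30e-5p and 0.0203 for miR-494. With cattle names only it was -0.0116 for miR-21-5p, -0.00964 for miR-200a and -0.0435 for miR-30e-5p, which was -0.0221 with identical values counted once. Without 1 library the ranges were -0.0528 to 0.133 for miR-21-5p, -0.183 to 0.0410 for miR-192, -0.0400 to 0.0414 for miR-191, -0.143 to 0.0139 for miR-22-3p and -0.101 to 0.0790 for miR-499. They were -0.0235 to 1.81 for miR-206, -0.0246 to 0.140 for miR-200a, -0.0175 to 0.175 for let-7b, -0.0485 to 0.0924 for miR-30e-5p, -0.101 to 0.283 for miR-127 and -0.149 to 0.00789 for miR-494.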

Other observations

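The miRNAs of the next 2 paragraphs were chosen only after their values were seen, and edgeR called none with all libraries. The 5' product of miR-1285 stood at 5.56 ± 3.0 against 24.0 ± 15.7 CPM in heat stressed and heat resistant cows (SD, n = 6 each; log2 fold change -2.09 ± 0.44, SE). A product of miR-6240 stood at 57.4 ± 9.24 against 112 ± 41.0 CPM (SD, n = 6 each). Log2 fold changes were -1.16 ± 0.30 and -0.99 ± 0.26 for 2 forms of miR-1260a and -0.72 ± 0.23 for miR-1260b (SE). miR-1246, whose sequence is also found in U2 snRNA, stood at 1125 ± 385 against 2312 ± 1449 CPM (SD, n = 6 each). Without heat resistant library 4 edgeR called the products of miR-1285 (adjusted p = 0.00656) and miR-6240 (0.0106), both forms of miR-1260a (0.0240 and 0.0245), miR-1260b (0.0422) and miR-1246 (0.0334), and DESeq2 called these 6 with all libraries. The product of miR-1285 was also called without heat stressed library 2 (0.0364) and that of miR-6240 without heat resistant library 5 (0.0293).

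Less abundant forms of lymphocyte miRNAs lay on both sides. A miR-150-5p form stood at 6.09 ± 3.25 against 2.28 ± 0.541 CPM and miR-342-5p at 52.1 ± 13.2 against 31.2 ± 6.91 CPM (SD, n = 6 each). Log2 fold changes were -0.67 ± 0.43 for miR-29b-5p, -0.64 ± 0.28 for miR-138-1-3p and -0.41 ± 0.21 for miR-26b-3p (SE). Of miRNAs of inflammatory responses, miR-132 had a log2 fold change of -0.38 ± 0.14 and miR-125a of -0.84 ± 0.37 (SE). Without heat resistant library 4 edgeR called miR-342-5p (adjusted p = 0.0182), the miR-150-5p form (0.0280) and miR-125a (0.0442). The first 2 were also called without heat stressed library 2 (0.0170 and 0.0389) and by DESeq2 with all libraries. The arm ratio of miR-211 differed by -2.10 ± 0.55 (log2, SE; limma adjusted p = 0.0745).

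Chance as the source of the counts was tested with 100 splits of the 12 libraries into 6 and 6, the real one among them. For features with an unadjusted p under 0.05 it is unlikely but not excluded. The real groups gave 146, the highest of the other splits 106, and only the real split, 1 of 100, gave as many. The 100 were a draw from the 462 possible splits, so splits that were not drawn could give as many. miRNAs that move together add to this count together, so it does not show a difference spread over many independent miRNAs. With the miR-451 to miR-23a ratio as a covariate the smallest adjusted p was 0.471 (edgeR). Chance cannot be excluded for the 4 lists past the threshold, where 43 of the splits gave as many and the highest gave 7. For the 0 called miRNAs and the 0 called arm ratios the splits decide nothing, since all 100 give at least 0; the highest counts were 2 and 1.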
